A study of Mus musculus with 11 samples.

How the data were processed

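HTT ChIP-seq was made from the striatum of male mice aged 4 months, with chromatin cut by micrococcal nuclease and sonication and an antibody against HTT, per the labels' protocols. The labels give 4 Q111/+ and 3 WT libraries, and 2 input libraries of each genotype, made without antibody, which were not analysed here. Bowtie2 2.2.5, MACS2 2.1 and the mouse build mm9 are named in the submitters' processing notes, which give them no role or order. The names of the deposited lists show paired reads and peaks called by MACS at a p of 0.001, with 1 list per library. Whether input served as control is not given in the sources used here.

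The deposited lists are in narrowPeak format. The authors' fold column gives each peak's ratio to its local background. The authors' significance columns hold the −log10 of the p-value and of the q-value. The authors' score column is a whole number derived from the −log10 p and was not analysed further. Fold and −log10 values belong to a peak within its own list, and were used to describe, rank or filter peaks there. Total read numbers are not in the lists, so depth is unknown and no counting interval is given for it.

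Peaks on the 19 autosomes, X and Y were used, and coordinates are 1-based in mm9. For size-matched lists, the 88920 peaks with the highest −log10 p were taken from each list, which is the length of the shortest one. Ties were ordered by fold and then at random with seed 11. Overlapping peaks of the 7 lists (at least 1 bp) were merged into regions, and a library called a region when 1 of its peaks overlapped it. Groups were compared by exact permutation over the 35 splits of 7 libraries into 4 and 3, whose smallest p is 0.0286. Chance recurrence came from 100 seeded shifts of each list along its chromosomes, and from shifts of blocks that keep regional density. Dense windows were the 1 Mb windows with 20 or more regions called in at least 4 libraries, a definition made after seeing the data. Chromosome shares were adjusted over 21 chromosomes by the Benjamini-Hochberg method. The regions named were fixed by a rule before the data were examined. They were the 10 called in all 7 libraries whose lowest percentile rank of −log10 p over the libraries was highest, and, by the same ranking among the libraries calling them, the 5 called in all Q111/+ and no WT library and the 5 called in all WT and no Q111/+ library.

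The number of fragments at a summit was recovered from each peak's deposited fold and −log10 p, a step added after seeing the data. In MACS the fold is the scaled pileup plus 1 over the local background plus 1, and the p-value is a Poisson tail of the scaled pileup. For each library a scale was found at which the pileup was a whole number of fragments, searched up to 60 fragments and a −log10 p of 60 with a tolerance of 0.02 in −log10 p. At least 99.9% of the peaks with a −log10 p of at most 60 in every library matched, against 1.27% to 5.48% with a wrong scale. A Poisson p of the unscaled fragments was then computed. Peaks with a −log10 p over 60 were not searched and were counted as passing each limit on it. Having no recovered fragments, they were left out of the local background values. On simulated data the fragment number was right in at least 99.6% of peaks, and of the simulated regions 93% of 200 set in the Q111/+ lists alone, 90.3% of 300 set in the WT lists alone and 100% of 400 set in all 7 were found.

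The alternatives were other thresholds, list lengths, rankings and overlap rules, absence judged in the full lists, autosomes alone, each library left out in turn, a replicate block and a batch block. Added after seeing the data were the unscaled fragment p-values, another random seed and the removal of dense windows. Tests of promoters and of gene lists had been planned and were not run, because no mm9 gene annotation was used here and coordinates were not converted between builds. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.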

Results

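Binding of huntingtin (HTT), the protein whose expanded glutamine tract causes Huntington's disease, was mapped by ChIP-seq in the striatum, the brain region most affected in that disease. The mice were 4-month-old males carrying 1 knock-in allele with an expanded CAG repeat (Q111/+) or 2 wild-type alleles (WT). Peak lists of 4 Q111/+ and 3 WT libraries were analysed, 1 list per library. The 4 input libraries, made without antibody, were not analysed here. The lists held between 88920 and 495334 peaks, and the sequencing depth of the libraries is unknown. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical. The names of the deposited lists carry 2 prefixes whose meaning is not given in the sources used here. They are treated as 2 batches, with Q111/+ replicates 1 and 2 and WT replicate 1 in batch 1, and Q111/+ replicates 3 and 4 and WT replicates 2 and 3 in batch 2.

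The comparison of list length asked whether HTT peaks were called as often in the mutant as in the WT striatum. Fewer peaks were called in every Q111/+ library than in any WT library. The Q111/+ lists held 104196 ± 10472 peaks (SD, n = 4) and the WT lists 293897 ± 183158 (SD, n = 3). On the log2 scale the Q111/+ lists were lower by a difference of -1.31, a 2.47-fold excess in WT (two-sided exact permutation test over 35 splits, p = 0.0286, the smallest this design allows). Peaks covered 23.6 ± 3.36 Mb in Q111/+ and 69.9 ± 48.8 Mb in WT, a log2 difference of -1.33 (exact permutation p = 0.0286). No difference in the size of the peaks was detected. Mean width was 226 ± 15.4 bp in Q111/+ and 230 ± 19.8 bp in WT (exact permutation p = 0.771), and the median of the authors' fold enrichment was 3.11 ± 0.313 and 3.10 ± 0.0987. WT replicate 1 had the longest list, and without it the log2 difference was -0.83 for peak number and -0.79 for covered length. Leaving out any 1 library gave exact permutation p-values of 0.0667 to 0.1, the smallest that the reduced designs allow. Keeping only peaks with a −log10 q of at least 2 gave log2 differences of -1.26 and -1.30 (exact permutation p = 0.0571). The genotypes then overlapped, since Q111/+ replicate 1 kept 107829 peaks and WT replicate 3 kept 104423. Within batch 1 the Q111/+ lists held 88920 and 111287 peaks and the WT list 495334, and within batch 2 they held 105854 and 110722 against 137373 and 248983. The mean within-batch log2 difference was -1.54 for peak number (exact permutation within batches, p = 0.0556, the smallest possible).

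Most peaks rested on few sequenced fragments. The deposited fold enrichments and p-values matched whole numbers of fragments multiplied by 4.20 to 6.16, which gave the number of fragments at a peak. The median peak held 5 fragments in 5 libraries and 4 in WT replicates 1 and 2, over a background of 1.14 to 1.65 fragments per position. With the fragments unscaled and a Poisson p of at most 0.001, the Q111/+ lists kept 10293, 7356, 5644 and 5944 peaks and the WT lists 32457, 11665 and 19304. The log2 difference was then -1.45 (exact permutation p = 0.0286). That p uses each library's own background, lower on average in WT (1.27 against 1.47 fragments per position). Among peaks of 8 to 9 fragments the genotypes overlapped. WT replicate 2 held 3500 such peaks, and WT replicates 1 and 3 held 10329 and 7539. Q111/+ replicates 1, 3 and 4 held 3807, 4805 and 4875, and replicate 2 held 2507. Peaks with more fragments recurred more often in other libraries. Among peaks of up to 4 fragments, 13.7% to 15.9% overlapped a size-matched peak of another library, and among peaks of 10 or more 77.5% to 94.9% did so.

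**Figure D1:**
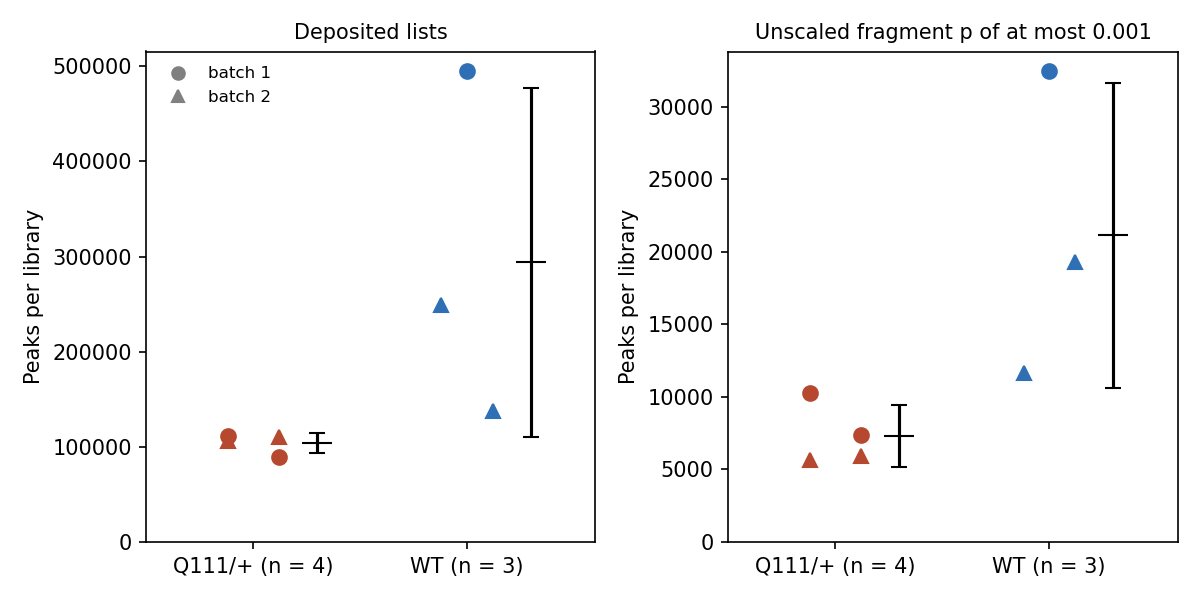
Peaks per library in the deposited lists (left) and among peaks whose unscaled fragments had a Poisson p of at most 0.001 (right). Each point is 1 library, circles are batch 1 and triangles batch 2, and the bars show the mean and SD of 4 Q111/+ and 3 WT libraries. In both panels every WT library lies above every Q111/+ library. The limit on the right uses each library's own background.

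**Figure D2:**
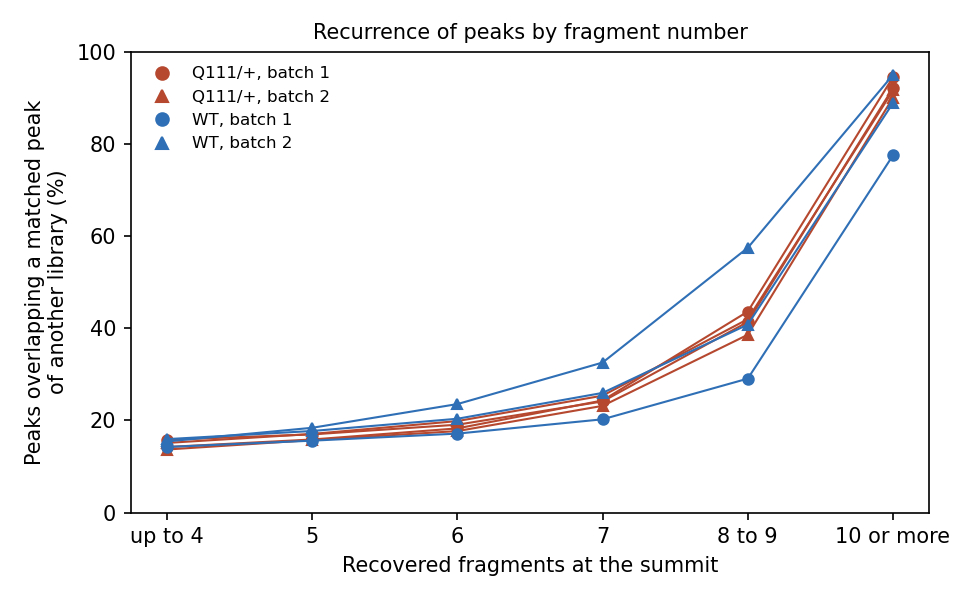
Percent of a library's peaks that overlapped a size-matched peak of another library, by the recovered number of fragments at the summit. Each line is 1 library. The percentage lay between 13.7 and 15.9 for peaks of up to 4 fragments and between 77.5 and 94.9 for peaks of 10 or more.

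Peaks that recurred in every library were few, and many lay in particular places. No peak list of an input was compared, so recurrence alone does not show HTT binding. Lists of equal length were compared, made of the 88920 peaks with the highest −log10 p of each library. They reached down to a −log10 p of 3.00 to 4.83 in the Q111/+ lists and of 11.6, 6.98 and 5.72 in WT replicates 1, 2 and 3, so they held 79.9% to 100% of the peaks of a Q111/+ list and at most 64.7% of those of a WT list. They merged into 536380 regions, of which 483282 (90.1%) were called in 1 library and 1100 in all 7. When the lists were shifted along each chromosome 100 times, a mean of 1.25 regions (range 0 to 5) fell in all 7. When blocks were shifted by 10 to 100 kb, which keeps regional density, the mean was 48.3 (range 30 to 71). The regions called in all 7 libraries had a median width of 1330.5 bp, against 190 bp for those called in 1 library. Since a region is the union of its overlapping peaks, its width grows with the number of libraries by construction. The X chromosome held 303 of the 1100 regions (27.5%) and the Y chromosome 47. Of the 6209 regions called in at least 4 libraries, 39.4% lay in 31 windows of 1 Mb, out of 2584 windows with any region. The densest were at 145000001 to 147000000 on chromosome 4, with 209 and 263 such regions, and at 120000001 to 123000000 on the X chromosome, with 229, 258 and 180 (mm9). These 31 windows held 53.1% of the regions called in all 7 libraries. The count of 1100 became 516 without these windows, 691 when peaks were ranked by fold enrichment, and 365 with 10000 peaks per list. It became 319 among peaks with an unscaled fragment p of at most 0.001, and 242 in lists of equal length ranked by that p.

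The regions ranked highest in all 7 lists included 3 on chromosome 2 (mm9), at 98506415 to 98507473, 98502404 to 98503126 and 98503852 to 98504225. In the first of these the authors' fold enrichment was 6.84 ± 0.608 (SD, n = 4) in the Q111/+ and 6.32 ± 1.31 (SD, n = 3) in the WT lists. Its −log10 p ran from 40788.4 to 87247.1 over the 7 lists. On chromosome 9 a region of 38299 bp at 3000011 to 3038309 had fold enrichments of 3.78 ± 0.461 and 3.60 ± 0.919, and a second region lay at 35112825 to 35113172. The −log10 p of the region of 38299 bp ran from 5619.62 to 19142.1. By the formulas of MACS given above, such values at such folds imply a local background far above the genome-wide one. Fragments were not searched at the 10 regions ranked highest. Sequence with extra copies relative to the reference therefore cannot be told apart from binding there. At 13743555 to 13746051 on chromosome 17 the fold enrichment was 5.35 ± 0.239 in the Q111/+ lists and 10.6 ± 0.787 in the WT lists. At 74665920 to 74668429 on chromosome 13 it ran from 3.93 to 5.78 in the Q111/+ lists and was 8.93 ± 1.71 in the WT lists. With peaks ranked by fold enrichment 4 of the 10 regions were called in all 7 libraries. The lists were called separately, and these fold values were not tested between genotypes. The other regions of the 10 ranked highest were at 3016692 to 3018689 on chromosome 4, 29697725 to 29699134 on chromosome 6 and 75904901 to 75905475 on chromosome 12. No gene annotation of mm9 was used here, so genes at these positions are not named.

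Regions called in every library of 1 genotype and in none of the other were more numerous for WT. In the size-matched lists, where the WT lists have the stricter limits, 418 regions were called in all 3 WT and no Q111/+ library, and 58 in all 4 Q111/+ and no WT library. Over all 35 splits of the 7 libraries into 4 and 3, the means of these counts were 176.6 and 69.0. No other group of 3 reached 418, the next highest being 355 for Q111/+ replicate 4 with WT replicates 2 and 3. The count of 58 was reached by 17 of the 35 splits, the real one included. Among the 18 splits that keep the batches, 418 was also the highest (exact permutation p = 0.0556, the smallest possible). Libraries also differed in how often they called recurrent regions, which a model with 1 weight per library allows for. Under it the WT trio had 1.40 times the expected regions (rank 3 of 35). The Q111/+ group of 4 had 2.48 times the expected regions (rank 1 of 35), but rank 5 in lists ordered by unscaled fragment p. Unequal call rates therefore remain a possible explanation of the WT count. The 5 WT regions named by the fixed rule were at 71313026 to 71313190 on chromosome 17, 9833563 to 9833814 on chromosome 13, 100883732 to 100883880 on chromosome 12, 56463031 to 56463216 on chromosome 18 and 81818315 to 81818794 on chromosome 6. None of these had a peak in any full Q111/+ list. With peaks ranked by fold enrichment 2 of the 5 were called in all 3 WT libraries, and the region on chromosome 18 in 0. At the first the authors' fold enrichment was 3.49 ± 0.0995 (SD, n = 3), and at the last the WT libraries held 19, 20 and 29 fragments with a fold enrichment of 3.66 ± 0.0746 (SD, n = 3). The 5 Q111/+ regions included 96050389 to 96050837 on chromosome 4, with 24, 14, 24 and 20 fragments and a fold enrichment of 4.42 ± 0.894 (SD, n = 4). Others lay at 145448004 to 145449488 on chromosome 4 and 120761536 to 120762741 on the X chromosome, and these 3 had no peak in any full WT list. The remaining regions, at 2590186 to 2590614 on the Y chromosome and 12586459 to 12587698 on chromosome 8, each had a weaker peak in 1 full WT list. The second of the regions on chromosome 4 and those on the X and Y chromosomes lay in dense windows. With peaks ranked by fold enrichment, or with 10000 peaks per list, 3 of these 5 regions were called in 4 libraries. Within batch 2, where 2 libraries stood against 2, 4136 regions were called in both WT libraries alone and 2894 in both Q111/+ libraries alone. Of the 6 splits of batch 2 the real one gave the most WT regions, and 3 gave at least as many Q111/+ regions as the real one. With 6 splits a share under 0.05 cannot be had. Batch 1 holds 1 WT library, so no count of shared WT regions can be had there.

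**Figure D3:**
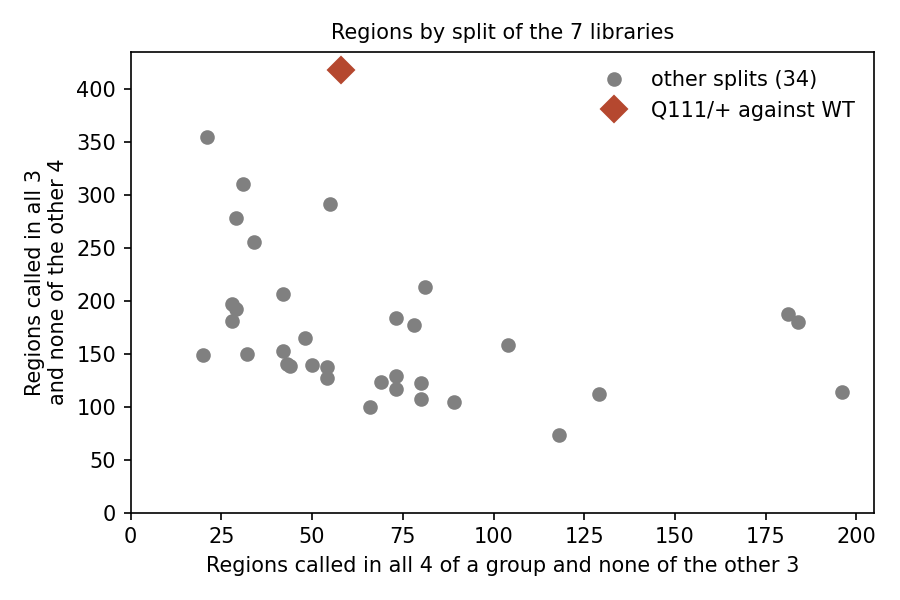
Regions called in all 4 libraries of a group and none of the other 3 (horizontal) against regions called in all 3 of the others and none of the 4 (vertical), for all 35 splits of the 7 libraries. The real split (diamond) has 58 and 418, the highest vertical value, and the next highest is 355.

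These counts rose when fewer libraries had to call a region or to lack it. Requiring 2 WT libraries in place of 3 gave 3236, 3081 and 2704 WT regions without WT replicates 1, 2 and 3, and the WT count was 651 without Q111/+ replicate 2. Requiring 3 Q111/+ libraries gave 242, 246, 173 and 171 Q111/+ regions without Q111/+ replicates 1, 2, 3 and 4, and the count was 123 and 108 without WT replicates 2 and 3. Without Q111/+ replicate 2, whose list was the shortest, the size-matched lists held 105854 peaks each. The counts of 246 and 651 therefore also come from longer lists. In the full lists, which differ in length, the counts were 3447 for WT and 29 for Q111/+, and among the 10000 highest peaks per list they were 158 and 14.

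No closer overlap among lists of 1 genotype than among lists of different genotypes was detected in the size-matched lists. The base-pair Jaccard index, the overlap of a pair of lists as a share of all positions in either, averaged 4.79% for pairs of the same genotype and 4.49% for pairs of different genotypes (one-sided exact permutation test, p = 0.171). WT pairs ranged from 5.69% to 7.60%, all above the mixed pairs, which ranged from 3.23% to 5.65%. Q111/+ pairs ranged from 3.34% to 4.90%, and their mean of 3.92% was below the mean of the mixed pairs. The test averages WT and Q111/+ pairs together and was not run for either alone. Pairs of the same genotype averaged 5.38% within a batch and 4.50% across batches, and pairs of different genotypes 4.75% and 4.22%. The difference of 0.30 percentage points became -0.44, -0.08 and -0.08 without WT replicates 1, 2 and 3. Without Q111/+ replicates 1, 2, 3 and 4 it was 0.85, 0.62, 0.66 and 0.76 (exact permutation p = 0.1 for each). It was 0.66 (exact permutation p = 0.0286) for all peaks with a −log10 p of at least 5, and 3.72 (exact permutation p = 0.0286) for all peaks with an unscaled fragment p of at most 0.001, and the lists differ in length in both. In lists of equal length it was 1.84 (exact permutation p = 0.0857) with 10000 peaks per list and 2.28 (exact permutation p = 0.114) when ranked by unscaled fragment p.

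The spread of peaks over the chromosomes differed between the 2 batches more than between genotypes. Over all 35 splits, no difference between Q111/+ and WT in the share of size-matched peaks was detected for any of the 21 chromosomes. The lowest raw exact permutation p was 0.0857 and the lowest Benjamini-Hochberg adjusted p was 0.66, with 0 chromosomes at an unadjusted p under 0.05. Within both batches, however, every Q111/+ library lay on the same side of every WT library for 8 chromosomes, a check made after seeing the data, where chance gives 11.1% of 21, or 2.33. Chromosomes 3, 14, 16, 18 and Y held a higher share in Q111/+ and chromosomes 4, 5 and 7 a lower one. The mean within-batch difference was 0.731 percentage points for chromosome 3 and -0.321 for chromosome 7 (exact permutation within batches, p = 0.0556, the smallest possible, and p = 0.111), and the lowest adjusted p was 0.292. Between batches, 10 chromosomes reached the smallest possible exact p of 0.0286, with an adjusted p of 0.06. Even 10 chromosomes at that p thus fell short of 0.05, so the adjusted test could not call a few chromosomes between genotypes either. Chromosome 11 held 5.50 ± 0.162% of peaks in batch 1 (SD, n = 3) and 3.84 ± 0.251% in batch 2 (SD, n = 4). Chromosome 2 held 7.29 ± 0.322% and 6.18 ± 0.102%, and chromosome 9 held 5.56 ± 0.146% and 4.54 ± 0.196%. The X chromosome, present as 1 copy in males, held 1.82 ± 0.199% and 3.01 ± 0.129%, which was 0.287 and 0.474 of its share of the covered span. In windows of 1 Mb, 100 of 2545 (3.93%) had peak numbers that did not overlap between genotypes, and 9 of the 35 splits gave as many. Chance gives 5.71% where no peak numbers are tied, and the median of the other splits was 41.5 windows. The 2 batches did not overlap in 1321 windows (51.9%).

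**Figure D4:**
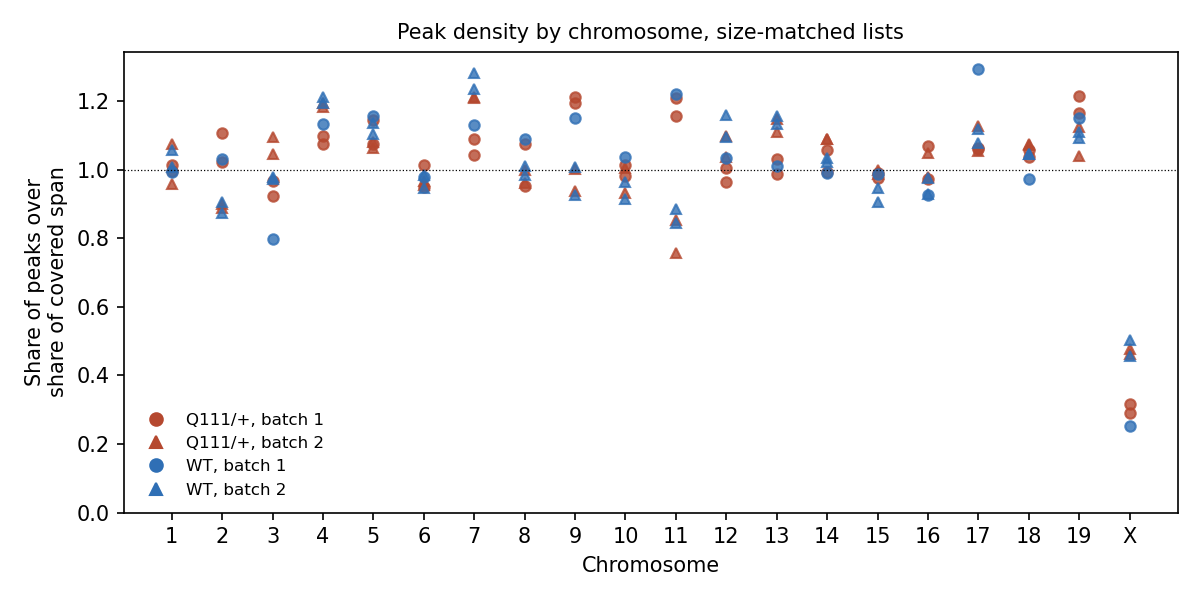
Share of a library's 88920 size-matched peaks on each chromosome, divided by the chromosome's share of the covered span. Each point is 1 library, red for Q111/+ and blue for WT, with circles for batch 1 and triangles for batch 2. The Y chromosome is not drawn. On chromosome 11 the batch 1 libraries lie above those of batch 2, and on the X chromosome below.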

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

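The tests of depth and of library call rates for the Q111/+ count were chosen after the results were seen, as were the unscaled fragment p-values. The batch block and the comparison with other splits were planned, but the values that would count against each explanation were set afterwards. Of 31 measures compared among the 4 Q111/+ libraries, 1 had a library far from the others, and chance gives about 1 in 20. Q111/+ replicate 4 had 4.02% of its size-matched peaks on chromosome 17, against 3.77% to 3.80% in the other Q111/+ libraries.

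The WT lists were longer than the Q111/+ lists. Scaled fragment counts are argued against as the whole cause, since at an unscaled fragment p of at most 0.001 the log2 difference was -1.45. Every WT list stayed longer, though the margin between 10293 and 11665 peaks was narrow. That p uses each library's own background, lower on average in WT (1.27 against 1.47). Of peaks with 8 to 9 fragments, WT replicate 2 held 3500. Q111/+ replicates 1, 3 and 4 held 3807, 4805 and 4875, and replicate 2 held 2507. WT replicates 1 and 3 held more than any Q111/+ library, 10329 and 7539. A part played by scaling is therefore not excluded. Unequal batches are argued against by the within-batch log2 difference of -1.54, with every WT list longer than every Q111/+ list in both batches. The size of that mean leans on batch 1, where the difference was -2.32 with 1 WT library, against -0.77 in batch 2. A difference in depth stays open. Background fragments per position, a stand-in for depth, differed by -0.203 (WT minus Q111/+, exact permutation p = 0.2). This direction is opposite to a greater depth of the WT libraries. The genotypes overlapped, with 1.30 to 1.65 in the Q111/+ and 1.14 to 1.44 in the WT libraries, so the question is not decided. Genotype stays open as a hypothesis, as do the yield of the precipitation and any input used as control, which were not tested.

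More regions were called in all WT and no Q111/+ library than the reverse. For the 418 WT regions 1 of the 35 splits, the real one, gave as many and the highest other gave 355. This argues against chance and does not exclude it (exact permutation p = 0.0286, the smallest possible). The 18 splits that keep the batches are too few for a share under 0.05 (exact permutation p = 0.0556). For the 58 Q111/+ regions chance cannot be excluded, since 17 of 35 splits gave as many and the highest other gave 196. Weakly supported peaks are argued against for the WT count, since at an unscaled fragment p of at most 0.001 there were 363 regions against 100 in the highest other group of 3, in lists of unequal length, and 116 against 65 in lists of equal length. Library call rates remain a possible explanation of the WT count, because with 1 weight per library the WT trio had 1.40 times the expected regions and ranked 3 of 35, with 1.51 and rank 2 once batch is added, 1.33 and rank 4 outside dense windows and rank 3 among lists ordered by unscaled fragment p, where 116 regions stood against 55.2 expected, and the stricter limits of the size-matched WT lists, which were not tested apart, stay open too. For the Q111/+ group the ratio was 2.48, 2.56 with batch and 2.65 outside dense windows, each rank 1 of 35, but it was 2.18 and rank 5 among lists ordered by unscaled fragment p, where 6 regions stood against 2.75 expected, so call rates and genotype cannot be told apart there.

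Recurrent regions clustered in 31 windows of 1 Mb. Sequence with extra copies relative to the reference could raise the local background of such windows. As the cause they would give a median local background over 1.5 times the genome-wide one in every library, and a value of at most 1.1 in the median library would count against them. The medians ranged from 1 to 1.36, with 1.16 in the median library. They cover only peaks with recovered fragments. The peaks with the highest −log10 p were not searched and were left out, which could lower the medians. Extra copies therefore cannot be told apart from binding there. Among peaks with recovered fragments, 21.4% to 43.9% of those inside the windows had a local background over 1.5 times the genome-wide one. Outside, 1.97% to 6.20% of all such peaks and 18.5% to 29.9% of the recurrent ones did. No biological explanation was tested.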

How the results depend on the processing

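The unscaled fragment p-values, another random seed and the removal of dense windows were chosen after seeing the data. Counting each result under each alternative, with counts judged by size and not by p, 66 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 29 counts moved further, 20 differences in list length lost and 2 Jaccard differences gained a call, and 3 reversed, while of the values for named regions 80 were the same and 20 moved. Unless stated, the cause of a change was not tested. Keeping peaks with a −log10 q of at least 2 gave log2 differences of -1.26 for peak number and -1.30 for covered length (exact permutation p = 0.0571 for both). Peak numbers then overlapped, with 107829 in Q111/+ replicate 1 and 104423 in WT replicate 3. Leaving out each library in turn gave -1.76 to -0.83 for peak number and -1.84 to -0.79 for covered length, and the calls ended because fewer libraries were compared. The same step gave -0.44 to 0.85 for the Jaccard difference, which reversed without WT replicates 1, 2 and 3 (-0.44, -0.08 and -0.08), 78 to 246 Q111/+ regions, 548 to 3236 WT regions (exact permutation p = 0.05 to 0.0667) and 1135 to 1489 regions in all remaining libraries. The values of 246 and 1489 came without Q111/+ replicate 2, where the size-matched lists were longer (105854 peaks). In lists of unequal length the Jaccard difference was 0.66 at a −log10 p of at least 5 and 3.72 at an unscaled fragment p of at most 0.001, both past the threshold (exact permutation p = 0.0286). It was 0.60 with all deposited peaks (exact permutation p = 0.0571).

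The number of Q111/+ regions was 29 with all deposited peaks, 14 with 10000 peaks per list, 24 at a −log10 p of at least 5, 767 where 1 library may depart, 25 with absence in the full lists, 8 at an unscaled fragment p of at most 0.001, 6 ranked by that p and 34 without dense windows. The number of WT regions was 3447 with all deposited peaks, 158 with 10000 peaks, 2159 at a −log10 p of at least 5, 8777 where 1 library may depart and 116 ranked by unscaled fragment p. Regions in all 7 libraries numbered 365 with 10000 peaks, 691 ranked by fold, 319 at an unscaled fragment p of at most 0.001, 242 ranked by that p and 516 without dense windows. Requiring a summit in the region changed nothing by construction. With a library left out, no chromosome could pass the threshold, since the smallest p was 0.0667 or 0.1.

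The replicate numbers in the titles did not pair the samples, and for the WT libraries they differ from the numbers in the names of the deposited lists. Deviations of same-numbered libraries correlated at 0.80, -0.73 and 0.59 for numbers 1, 2 and 3. With the replicate block, which leaves out Q111/+ replicate 4, the log2 differences were -1.34 and -1.37 (exact permutation p = 0.25, the smallest of 8 exchanges), the Jaccard difference 0.76, and the regions 171 for Q111/+, 618 for WT (exact permutation p = 0.125, the smallest for this count) and 1199 in all. With the batch block the log2 differences were -1.54 and -1.60 and the WT regions 418 (exact permutation p = 0.0556 for each, the smallest possible). The promoter and gene list tests were not run. Unknown depth limits what the absence of a peak shows, since the median peak held 4 or 5 fragments.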

Other observations

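The X chromosome held a rising share of regions with the number of libraries that called them, much of it in a few places. It held 1.23% of the regions called in 1 library, 4.95% of those called in 3, 15.3% of those called in 5 and 27.5% of those called in all 7. Of the regions called in at least 4 libraries, 747 of 986 on the X chromosome lay in 6 dense windows and 159 of 161 on the Y chromosome in 2. Outside the dense windows the X chromosome held 1.14%, 2.82%, 7.01% and 8.53% of the regions called in 1, 3, 5 and all 7 libraries, and the Y chromosome held none of those called in all 7. Among autosomes, chromosome 1 held 155 and chromosome 4 held 106 of the regions called in all 7 libraries, and chromosome 11 held 19.

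The regions of each genotype were set beside regions called in as many libraries of other groups. The X chromosome held 5.02% of the 418 regions called in all WT and no Q111/+ library and 4.95% of the 5763 called in another group of 3, and it held 8.62% of the 58 called in all Q111/+ and no WT library and 8.91% of the 2358 called in another group of 4. The Y chromosome held none of the 418 against 46 of the 5763, and 5 of the 58 against 41 of the 2358, differences that were not tested. Dense windows, which regions of 4 or more libraries define, held 41.4% of the 58 against 30.5% of the 2358, and 13.6% of the 418 against 19.6% of the 5763. Median width was 602.5 bp for the Q111/+ regions and 600.5 bp for the WT regions, against 694 bp in the other groups of 4 and 490 bp in the other groups of 3.

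Peak shares of 8 chromosomes stood apart between genotypes on the same side in both batches. Of the 18 splits that keep the batches, 1, the real one, gave as many and the highest other gave 5. With 18 splits a share under 0.05 cannot be had. This test was chosen after the result was seen.

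Libraries of the same batch were alike in where their peaks lay along the genome. Over windows of 1 Mb, the rank correlation of peak numbers across windows, which are not independent replicates, was 0.43 to 0.84 for pairs of the same batch and -0.31 to 0.38 for pairs of different batches.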
